A study of Arabidopsis thaliana with 48 samples.

How the data were processed

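The samples were polysome fractions of 6-day-old Arabidopsis thaliana roots. Ribosomes that carry a FLAG tag, expressed from a chosen promoter, were immunopurified together with the mRNA bound to them (translating ribosome affinity purification), so that each library reads the mRNA engaged by ribosomes in the cells where the promoter is active. Seedlings grew in continuous light and received 100 nM brassinolide (BL), the most active brassinosteroid hormone, for 0, 3 or 8 h, per the labels' protocols. The tag was driven by the 35S promoter (whole root), by pBRN2 (root cap), by pGL2 (non-hair epidermis), by pSCR (endodermis) or by pSHR (stele) in Col-0 plants. It was also driven by pGL2 or pSCR in bri1-116 plants, which lack the brassinosteroid receptor BRI1, with BRI1 restored from pGL2 or pSCR. These lines are written with the tag promoter first and the BRI1 transgene in parentheses, as pGL2(pGL2BRI1), pGL2(pSCRBRI1) and pSCR(pSCRBRI1). The 8 lines at 3 times gave 24 groups of 2 libraries, 48 in all, which the series design describes as biological repetitions. The p-values rest on the spread between such pairs, pooled over all groups.

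Libraries were made with TruSeq RNA v2, a kit that does not mark strand, and sequenced on a HiSeq 2500 as 50 bp single-end reads, per the labels' protocols and the series design. A note on 21 libraries says that their reads were 51 bases long before the last base was trimmed. Reads were checked with FastQC 0.10.1, aligned to TAIR10 with TopHat2 2.0.9 and counted with HTSeq 0.5.3p3, and DESeq2 1.2.8 was used for normalization and testing, per the submitters' processing notes and the series design. The table the authors deposited holds whole-number read counts per gene, not normalized, and the tests were run on these counts. It has 33715 entries, each with its TAIR10 position. Of these, 7275 carry a transcript or protein suffix, 199 share a locus code with another entry and 283 lie on the organelle genomes. The table held 0 columns of other samples. Gene symbols came from a RefSeq gene table matched on the locus code, for 10689 entries, and coordinates from the deposited table.

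Total counts ran from 20556381 to 37685541 per library. Genes with low counts were removed with the filterByExpr function of edgeR, which left 20995 genes that held at least 99.98 percent of the counts of every library. Counts were scaled with TMM. The main test was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with 1 mean per group, all 48 libraries in 1 fit, robust estimation and Benjamini-Hochberg (BH) adjustment within each comparison. A gene passed at an adjusted p under 0.05. The common dispersion was 0.0485 and the median prior degrees of freedom were 6.2. Levels are in CPM, read counts scaled by the cpm function of edgeR to the TMM library size, as mean and SD of 2 libraries. Changes are log2 fold changes with standard errors (SE). There were 30 comparisons. Each Col-0 promoter line was set against the 35S line at 0 h, each BL time against 0 h of the same line, and the complemented lines against each other or against the Col-0 line with the same tag promoter at 0 h. Responses of paired lines were compared by the contrast of their fold changes. No untreated library of 3 or 8 h is analysed here, so every BL comparison joins the effect of BL with those of elapsed time and handling.

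Gene lists were fixed from background knowledge before the data were examined. The 23 lists held 279 members, of which 1 was dropped because its symbol and locus code disagreed, and 271 were tested. They covered cell type markers (root cap, non-hair epidermis, root hair, cortex, endodermis, stele and green tissue), brassinosteroid synthesis, breakdown and signalling, auxin synthesis, transport and response, ethylene, expansins and xyloglucan endotransglucosylase/hydrolases (XTH), cellulose synthesis, the cell cycle, touch and wounding, heat shock, and the circadian clock. For each list the members that passed were counted over all genes tested, and again adjusted over the list alone. Lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01 and BH over the lists of a comparison. Camera with an estimated correlation and fry were run as alternatives.

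The genes named were candidates under a rule fixed before the data were examined. In each comparison these were the 10 higher and 10 lower genes with the largest log2 change that passed, with a mean of at least 8 CPM in the higher group, a symbol and, except for response differences, libraries of both groups that did not overlap. List members could be named in any comparison, and BRI1 was reported in every group. After the values were seen, candidates with a group at or under 3 counts were passed over except SULTR1;1 in pSHR and ACS11 in pGL2, and candidates that recurred between lines were preferred. Genes without a symbol in the stele comparisons and in the response differences, where few genes passed, were also named after their values were seen. The standard errors and levels of named genes are given for the few that matter most.

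Alternatives chosen before the data were examined were the Wald test of DESeq2 1.42.0, RLE scaling, no filter on low counts, a fit of the compared groups only, the read note as a term, the replicate number as a block, the omission of each library in turn, and an added requirement of a 1.5-fold change. Alternatives chosen after the data were seen were the read note as a separate term for each line, a fit without the 6 libraries labelled pGL2(pSCRBRI1), a fit of the pGL2(pGL2BRI1) line with the read note libraries only, and a block with crossed replicate numbers. Fits that omit a library keep the dispersion trend of the full set and estimate the quasi-likelihood dispersions anew, and they assume that a lone library varies like the other groups. Replicate pairs were checked for duplicates. Their chi-square per degree of freedom over genes with at least 20 counts ran from 12.4 (pSHR at 8 h) to 162 (pBRN2 at 8 h), far above sampling noise. Pooling hides this range, so call counts do not rank lines by response.

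The test was checked on simulated counts for the pGL2 line at 8 h against 0 h over 20995 genes. Of 100 genes seeded at a log2 change of 1 in either direction 34 percent were recovered, with a median fitted size of 0.974. Of 100 genes seeded at 2, 97 percent were recovered, with a median of 1.92. False calls made up 2.96 percent of the calls, and 0 seeded calls had the wrong sign. Of random lists, 1.5 percent passed an unadjusted p of 0.05 in camera. Random lists do not test correlated ones such as mitosis (estimated correlation 0.559 in pBRN2 against 35S). Changes near 2-fold are therefore often missed with pairs of libraries. Genes of close families that share reads (XTH17 and XTH18, sks15 and its neighbours, SWEET11 and SWEET12, the cellulose synthases) are uncertain in their counts. So are genes that overlap another gene (CASP1, CDKB2;1, DET2, DGR2 and GL2), because the kit does not mark strand. The transcript of RPL18, the ribosomal protein that carries the tag in this method, was the most abundant in the pBRN2 libraries, in the 35S libraries except replicate 2 of 8 h, and in the pSHR libraries of 8 h, and may include transgene reads.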

Results

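Polysome-bound mRNA was measured in 48 libraries of Arabidopsis roots, 2 for each of 24 groups. The groups were 8 lines, each with a tag driven by 1 promoter, after 0, 3 and 8 h of BL. In all, 20995 genes were tested. Per the title and labels, the series asks how brassinosteroid signals differ between root tissues. The lines were therefore compared with the whole root before treatment, with themselves after BL, and with each other where the receptor was restored in 1 tissue. Values after ± are SD over 2 libraries for levels in CPM and SE for log2 changes, and a gene rose, fell or changed only where it passed the edgeR quasi-likelihood test with BH adjustment.

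BRI1 (AT4G39400, chromosome 4, 18324661 to 18328826, TAIR10), the brassinosteroid receptor, was read in every line. The bri1-116 allele changes the protein, and its transcript is still counted, so these counts do not separate the mutant transcript from the transgene. At 0 h BRI1 stood at 31.8 ± 2.59 CPM in 35S, 88.1 ± 12.9 in pBRN2, 32.9 ± 4.59 in pGL2, 17.3 ± 12.4 in pSCR and 12.9 ± 1.42 in pSHR. At 3 h it stood at 17.5 ± 7.8, 79 ± 18.1, 22.4 ± 3.63, 12.1 ± 6.28 and 8.53 ± 1.19 CPM in the same lines. At 8 h it stood at 14.8 ± 4.34, 69.6 ± 24.9, 24 ± 6.02, 10.8 ± 4.7 and 8.93 ± 0.0951 CPM. In pGL2(pGL2BRI1) it stood at 44 ± 11.4, 41.8 ± 8.43 and 46.3 ± 9.08 CPM at 0, 3 and 8 h. The libraries labelled pGL2(pSCRBRI1) held 18.5 and 21.9 CPM in the 0 h replicates, 23.1 ± 4.13 at 3 h and 34.8 ± 0.836 at 8 h, and pSCR(pSCRBRI1) held 19.9 ± 3.07, 23.9 ± 6.36 and 19.7 ± 1.46 CPM.

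Cell type markers followed the promoter of the tag in 7 lines and went against the label in the libraries labelled pGL2(pSCRBRI1). In the labelled 0 h libraries GL2, the homeodomain factor of non-hair cells whose promoter is named, was at 1.82 and 1.79 CPM against 86 ± 39.7 in pGL2. SCR, the endodermal GRAS factor, was at 203 and 239 CPM, and CASP1, a Casparian strip protein, at 2850 and 2220 CPM. The median endodermis marker was at 90.4 and 84.8 percent of its pSCR level, and the median epidermis marker at 2.75 and 2.98 percent of its pGL2 level. These libraries are called by their label throughout, and every direction drawn from them below compares an endodermal profile. In pGL2(pGL2BRI1) the endodermis markers were at 29.1, 13.7 and 29.5 percent of the pSCR level in replicate 2 of 0 h, replicate 1 of 3 h and replicate 2 of 8 h, which lack the read note, and at 1.82 to 2.62 percent in the other 3 libraries.

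**Figure D1:**
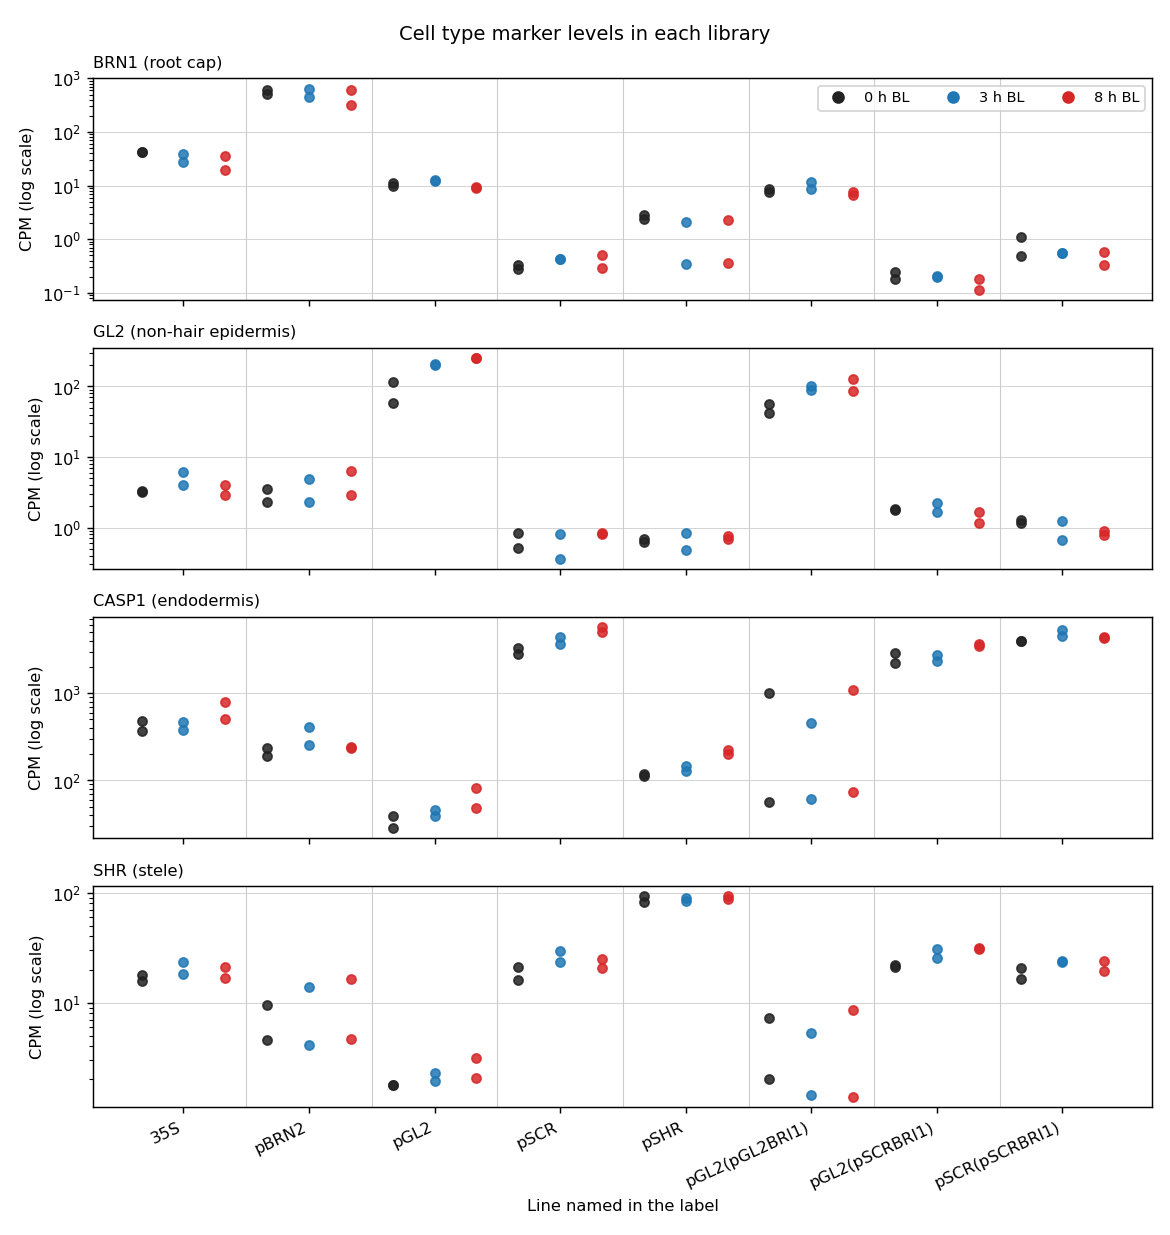
Level in CPM (log axis) of BRN1, GL2, CASP1 and SHR, markers of root cap, non-hair epidermis, endodermis and stele, in each of the 48 libraries, by line on the horizontal axis. Each point is 1 library, black at 0 h, blue at 3 h and red at 8 h of BL. The libraries labelled pGL2(pSCRBRI1) have GL2 near 1.8 CPM and CASP1 above 2000 CPM at 0 h.

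The pBRN2 (root cap) fraction was set against the whole root (35S) at 0 h. BRN1 (AT1G33280, chromosome 1, 12072741 to 12073833), BRN2 and SMB, the NAC factors that mature the root cap, were higher, BRN1 at 556 ± 60.9 against 42.2 ± 0.0208 CPM. The root cap cellulase gene CEL5 was at 2110 ± 26.1 against 254 ± 7.29 CPM, and MRD1 at 39.9 ± 11.4 against 0.47 ± 0.000302 CPM. FEZ, a NAC factor of root cap stem cells, was lower. Of the 7 root cap markers 6 were higher and 1, FEZ, was lower, the same adjusted over the list alone, with a median log2 change of 3.05 (camera with BH, adjusted p = 0.000209, and adjusted p = 0.155 with an estimated correlation). BAS1 and BEN1, which inactivate brassinosteroids, were higher by 2.22 ± 0.296 and 2.03 ± 0.277, as were 4 of the 5 genes of brassinosteroid breakdown (4 adjusted over the list alone, adjusted p = 0.00318 by camera with BH, and adjusted p = 0.155 with an estimated correlation). Stele markers were lower in 17 of 22 cases, with SUC2, the phloem sucrose transporter, at -1.94 ± 0.477 (adjusted over the list alone 17 lower and 1 higher, adjusted p = 1.31e-05 by camera with BH, and adjusted p = 0.155 with an estimated correlation). XTH20, EXPB3 and PAP2 were also lower, at -3.68, -3.42 and -3.92. In all, 3801 genes were higher and 4811 lower by the edgeR quasi-likelihood test with BH (44.1 percent of the calls higher under TMM and 51.1 percent under RLE), and BRN1 had a log2 change of 3.72 ± 0.506 at an adjusted p of 1.67e-06. The median log2 change of all genes was -0.14, which RLE scaling moved by 0.102, and FEZ no longer passed without pBRN2 replicate 1 (adjusted p = 0.0836).

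In the pGL2 fraction, the non-hair epidermis, GL2 (AT1G79840, chromosome 1, 30036956 to 30041440) was at 86 ± 39.7 CPM against 3.23 ± 0.0353 in the whole root. PDF1, a protodermal gene, NRT2:1, a nitrate transporter, and the epidermal regulators MYB23 and TTG2 were also higher, by 5.30, 4.80, 2.17 and 2.17 on the log2 scale. The genes of cellulose synthesis were higher as a group, 9 of 9 over all genes and adjusted over the list alone (camera with BH, adjusted p = 0.000258, and adjusted p = 0.313 with an estimated correlation). CESA1 was at 375 ± 76.7 against 164 ± 14.7 CPM, and CESA3 and CESA6 were higher by 1.38 and 1.33. Of the 7 epidermis markers 4 were higher (4 adjusted over the list alone, adjusted p = 0.00638 by camera with BH, and adjusted p = 0.313 with an estimated correlation). The markers of other tissues were lower: 12 of 13 for endodermis, 21 of 22 for stele with 1 higher, 7 of 7 for root cap, 3 of 3 for cortex and 8 of 11 for root hair, the same adjusted over the list alone except 9 for root hair. Their adjusted p by camera with BH were 0.00056, 1.27e-10, 0.00149, 0.0282 and 0.00981, and with an estimated correlation the adjusted p = 0.392, 0.0504, 0.313, 0.313 and 0.392. CEL5, the peptide gene RGF2 and NIC3, a nicotinamidase gene, were lower, at -5.45, -5.89 and -8.79, and SHR, the stele GRAS factor, at -3.24. In all, 4838 genes were higher and 5431 lower by the edgeR quasi-likelihood test with BH (47.1 percent higher under TMM and 51.9 percent under RLE), with GL2 at 4.73 ± 0.393 and an adjusted p of 9.9e-11. The median of all genes was -0.117, and a fit of the compared groups alone passed 7 epidermis markers.

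The pSCR fraction carried the endodermal mRNAs. SCR (AT3G54220, chromosome 3, 20070158 to 20072780) was at 225 ± 36.3 against 21.9 ± 0.716 CPM, CASP1 (AT2G36100, chromosome 2, 15159591 to 15160750) at 3060 ± 359 against 425 ± 79.7 CPM. MYB36, the factor that turns on Casparian strip genes, was higher by 2.75 ± 0.943. The acyltransferase genes GPAT6 and GPAT7 and the suberin wax gene FACT were higher by 4.06, 4.18 and 4.11, and the transporter gene ABCG16 by 4.45. Of the 13 endodermis markers 11 were higher and 1 lower, the same adjusted over the list alone (camera with BH, adjusted p = 0.000406, and adjusted p = 0.418 with an estimated correlation). Auxin genes were lower, 16 of 22 of auxin response and 7 of 9 of auxin synthesis (17 and 8 adjusted over the list alone), IAA19 at -2.84 ± 0.272 and SHY2 at -2.56 ± 0.297. These calls held with an estimated correlation, with adjusted p of 7e-06 and 0.00797, and of 0.000735 and 0.0182, by camera with BH. WER, the epidermal MYB factor, COW1, a root hair growth gene, and BRN1 were lower, at -4.88, -2.69 and -7.07. So were 7 of 7 epidermis, 10 of 11 root hair and 7 of 7 root cap markers and 18 of 22 stele markers, with 1 stele marker higher, the same adjusted over the list alone. The calls of root cap and stele held with an estimated correlation (adjusted p = 0.0182 for each, camera with BH), and those of epidermis and root hair did not (adjusted p = 0.0904 for each). Expansin and XTH genes were lower in 18 of 26 cases and higher in 2, the same adjusted over the list alone, with XTH17 at -4.34 (camera with BH, adjusted p = 3.31e-05, and adjusted p = 0.0904 with an estimated correlation). Of the synthesis genes of brassinosteroids, BR6OX2 was higher by 1.99 ± 0.552 and DWF4 lower, at -1.64 ± 0.49. In all, 2593 genes were higher and 4629 lower by the edgeR quasi-likelihood test with BH. Without either 35S replicate the higher count fell by a larger share than the lower. Fewer endodermis markers passed each time, and CASP1 and MYB36 did not. MYB36 also did not pass without pSCR replicate 2, nor BR6OX2 without 35S replicate 1 and DWF4 without pSCR replicate 1.

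In the pSHR fraction stele genes were higher. SHR (AT4G37650, chromosome 4, 17691786 to 17693760) was at 88.2 ± 7.53 against 16.8 ± 1.34 CPM, and XCP2, a xylem protease gene, at 833 ± 53.3 against 147 ± 1.05 CPM. The vascular regulator TMO5, the glutaredoxin gene ROXY1, the cytokinin genes HP6 and LOG3 and the brassinosteroid synthesis gene CPD were higher by 1.87, 4.62, 3.85, 3.44 and 2.04. Of the 22 stele markers 14 were higher (16 adjusted over the list alone, adjusted p = 3.99e-09 by camera with BH, and adjusted p = 0.0517 with an estimated correlation). Of the 21 mitosis genes 6 were higher and 1 lower, and of the 10 DNA replication genes 6 were higher (8 and 1, and 8, adjusted over the list alone). Their adjusted p by camera with BH were 0.00212 and 0.00301, and with an estimated correlation the adjusted p = 0.452 and 0.15. Root hair markers were lower in 10 of 11 cases, with EXPA7 at -3.11 ± 0.312 and COW1 at -2.97 ± 0.413. Likewise 6 of 7 root cap markers, 6 of 7 epidermis markers and 5 of 13 endodermis markers were lower, with 1 root cap marker higher (11, 6 with 1 higher, 6 and 10 adjusted over the list alone). Their adjusted p by camera with BH were 3.99e-09, 1.62e-05, 0.000388 and 0.0423, and with an estimated correlation the adjusted p = 0.0638, 0.0638, 0.107 and 0.587. BAS1 was lower, at -1.83 ± 0.302 with 4 of 5 breakdown genes, 4 adjusted over the list alone (camera with BH, adjusted p = 6.57e-05, and adjusted p = 0.0517 with an estimated correlation). The pectin oxidase-like gene sks15 and RGF2 were lower, at -6.51 and -7.14. In all, 1623 genes were higher and 3971 lower by the edgeR quasi-likelihood test with BH, with SHR at an adjusted p of 0.00294. A fit of the compared groups alone passed 9836 genes, 18 of them mitosis genes. Without any 1 of the 4 compared libraries the higher count fell by a larger share than the lower. Fewer mitosis and replication genes passed each time, and no endodermis marker did.

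Few genes passed after BL in the whole root (35S), with 2666 (3 h) and 2263 (8 h) at an unadjusted p under 0.05. XTH33 (AT1G10550, chromosome 1, 3479153 to 3480988), a cell wall enzyme gene, rose to 12.8 ± 1.55 from 4.4 ± 0.115 CPM at 3 h, and BEE1 (AT1G18400, chromosome 1, 6331398 to 6333743), an early brassinosteroid response factor, rose by 2.38 ± 0.381. WAG2, a kinase of auxin transport, YLS9, and BRU6, an auxin-conjugating enzyme, rose by 1.69, 2.30 and 1.55. BEH2 (AT4G36780, chromosome 4, 17332517 to 17334349), a brassinosteroid transcription factor, fell to 12.1 ± 2.49 from 36.9 ± 2.48 CPM. IDL1, a signal peptide gene, MYB55, the cytokinin response gene ARR3, the meristem factor AIL6 and the homeobox gene HAT1 fell, with changes of -1.84, -1.76, -1.61, -1.67 and -1.16. At 8 h BEE1 had risen by 2.51 ± 0.38, EARLI1 by 2.4 and BRU6 by 1.47, and MYB55 (-2.28 ± 0.319), IDL1 (-2.01), AIL6 (-2.01), ARR3 (-2.0) and BEH2 (-1.59) had fallen. In all, 30 genes rose and 35 fell at 3 h, and 35 rose and 55 fell at 8 h, by the edgeR quasi-likelihood test with BH, with BEE1 at adjusted p of 0.00237 and 0.000612. Green tissue markers were higher as a list at both times (camera with BH, adjusted p = 1.29e-07 and 6.22e-09, and adjusted p = 0.221 and 0.246 with an estimated correlation). Of these 13 genes 0 passed at either time over all genes by edgeR, 9 and 11 had an unadjusted p under 0.05, DESeq2 passed 1 and 3, and 8 and 11 passed adjusted over the list alone. Brassinosteroid synthesis genes were lower as a list at both times (camera with BH, adjusted p = 0.00143 and 0.00536, and adjusted p = 0.0656 and 0.121 with an estimated correlation), with 0 passing over all genes by edgeR, 4 and 2 at an unadjusted p under 0.05, 0 and 1 by DESeq2, and 0 and 1 adjusted over the list alone. Root cap markers were lower as a list at 8 h, with a median of -0.60 (camera with BH, adjusted p = 0.00536, and adjusted p = 0.246 with an estimated correlation), and -1.12 and -0.22 without replicates 1 and 2 of 8 h. Of these 7 genes 1 fell, 2 adjusted over the list alone, and 0 passed without either replicate of 0 h or replicate 2 of 8 h, and 2 without replicate 1 of 8 h. Of the 3 h genes named, each failed without at least 1 library. At 8 h BEE1, MYB55 and IDL1 passed without each library in turn. The counts moved without most libraries, as given below. The green markers that passed over all genes were 2 without replicate 2 of 3 h and 9 without replicate 1 of 8 h. DESeq2 passed 217 and 199 genes, and the compared groups alone 0 and 0.

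In the root cap fraction (pBRN2), XTH33 rose by 1.93 ± 0.275 at 3 h and the expansin gene EXPA17 rose to 395 ± 163 from 66.9 ± 5.01 CPM. The sucrose exporters SWEET11 and SWEET12 rose by 3.33 and 3.19, the auxin response gene IAA33 by 2.30 and the glutathione transferase gene GSTF6 by 3.01. BEH2 fell to 9.35 ± 0.615 from 43.5 ± 10.4 CPM, HAT1 to 71.3 ± 6.91 from 229 ± 52.1 CPM, and GH3.5, an auxin-conjugating enzyme, to 24 ± 0.0105 from 60.4 ± 0.775 CPM. TCH4, the touch-induced XTH gene, and MYB55 changed at -2.02 and -1.62. At 8 h the asparagine synthetase gene ASN1, MIOX4 and ERD5 rose by 3.95, 3.60 and 2.12 ± 0.32, and BEE1 by 2.27. LEA14, a late embryogenesis abundant gene, fell to 23.9 ± 3.31 from 161 ± 21.6 CPM, and IDL1, DGR2, BEH2 and the ethylene synthesis gene ACO1 fell, with changes of -2.08, -2.35, -1.65 and -1.23. In all, 94 genes rose and 98 fell at 3 h, and 115 rose and 121 fell at 8 h, by the edgeR quasi-likelihood test with BH, with LEA14 at an adjusted p of 3.49e-09. The auxin synthesis list was higher at 3 h with a median of 0.65, and of 0.28 without replicate 2 of 3 h (camera with BH, adjusted p = 0.0276, and adjusted p = 0.0763 with an estimated correlation). Of its 9 genes 0 passed over all genes by edgeR, 0 by DESeq2, 4 at an unadjusted p under 0.05 and 4 adjusted over the list alone. Stele markers were higher as a list at 8 h, with a median of 0.60 (camera with BH, adjusted p = 0.0018, and adjusted p = 0.839 with an estimated correlation). Of these 22 genes 0 passed by edgeR, 0 by DESeq2, 4 at an unadjusted p under 0.05 and 0 adjusted over the list alone, and the stele median was 0.10 to 0.98 without each library in turn. Replicate 2 of 8 h had a TMM factor of 1.05 and epidermis markers at 42.1 percent of their pGL2 level, against 0.791 and 22.4 percent in replicate 1. XTH33, BEH2, HAT1 and GH3.5 at 3 h and ERD5, LEA14 and IDL1 at 8 h passed without each library in turn. The other calls named failed without at least 1. The counts also moved, as given below. DESeq2 passed 365 and 470 genes, and the compared groups alone passed 0 and 38.

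In the non-hair epidermis (pGL2), genes of auxin synthesis rose after BL. YUC3 (AT1G04610, chromosome 1, 1279388 to 1281618), a flavin monooxygenase of auxin synthesis, rose to 140 ± 2.1 CPM at 3 h and 116 ± 7.81 at 8 h from 36.1 ± 2.48. YUC8 (AT4G28720, chromosome 4, 14192583 to 14194256) rose by 2.15 and 2.47, and YUC9 by 1.46 and 1.23. IAA19 (AT3G15540, chromosome 3, 5264024 to 5265678), an auxin response gene, rose to 27.1 ± 3.86 from 5.14 ± 0.61 CPM at 3 h and by 1.76 at 8 h. The sulfate transporter SULTR1;1 (AT4G08620) rose by 4.83 and 5.10, and BXL1, a wall xylosidase gene, by 2.83 and 4.27. XTH33 rose by 1.98 at 3 h and BEE1 by 1.79 and 2.75. At 8 h ASN1 rose by 4.96, DFL1, an auxin-conjugating enzyme, by 1.92, and GL2 itself to 255 ± 1.99 from 86 ± 39.7 CPM. BEH2 fell to 6.56 ± 1.09 CPM at 3 h from 48 ± 6.91, and MYB55 (AT4G01680, chromosome 4, 716004 to 717579) to 4.67 ± 1.59 CPM at 8 h from 51.5 ± 11.8. PUB29, ARR3 and PIN4, an auxin exporter, changed at -3.26, -2.99 and -1.34 at 3 h and -2.91, -2.90 and -1.24 at 8 h. DWF4, the rate-limiting enzyme of brassinosteroid synthesis, fell at 3 h (-2.44) with the growth inhibitor IBH1 (-1.92), and the synthesis gene DET2, the receptor gene BRL3 and the replication genes MCM2 and RNR1 fell at 8 h (-1.05, -1.86, -0.73 and -0.83).

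These pGL2 changes were part of 104 genes higher and 102 lower at 3 h and 387 higher and 426 lower at 8 h by the edgeR quasi-likelihood test with BH, with YUC3 at adjusted p of 7.76e-05 and 0.000517. Of the 9 auxin synthesis genes 3 rose at 3 h, and 3 rose and 1 fell at 8 h (4 higher at 3 h, and 3 higher and 1 lower at 8 h, adjusted over the list alone). The list was higher at both times also with an estimated correlation (adjusted p = 1.26e-05 and 0.00883 by camera with BH, and adjusted p = 0.00147 and 0.0397 with an estimated correlation). The brassinosteroid synthesis list was lower at both times (adjusted p = 0.000189 and 0.00748 by camera with BH, and adjusted p = 0.00805 and 0.0397 with an estimated correlation), with 1 gene passing at each time and 2 and 5 adjusted over the list alone. The 3 h gene did not pass without any 1 of the compared libraries, and at 8 h 2 and 0 passed without replicates 1 and 2 of 8 h. Auxin response genes rose in 3 cases at each time (4 higher with 1 lower at 3 h, and 4 higher at 8 h, adjusted over the list alone). Their list was higher by camera with BH (adjusted p = 0.0194 and 0.0192, and adjusted p = 0.221 and 0.162 with an estimated correlation). The DNA replication list was lower at 8 h with 2 genes passing and 4 adjusted over the list alone (camera with BH, adjusted p = 0.00981, and adjusted p = 0.318 with an estimated correlation). At 3 h 1 auxin synthesis gene passed without replicate 1 of 0 h, and 1 auxin response gene without replicate 2 of 0 h or replicate 1 of 3 h, while the compared groups alone passed 5. At 8 h 2 auxin synthesis genes passed without replicate 2 of 0 h or either replicate of 8 h, and 1 auxin response gene without replicate 2 of 8 h. The DNA replication genes were 1 and 0 without replicates 1 and 2 of 0 h and 0 without replicate 2 of 8 h or with the compared groups alone. Epidermis markers moved with these genes, at 110 and 90.3 percent of their mean pGL2 level in the 0 h replicates, 159 and 154 percent at 3 h and 114 and 180 percent at 8 h. They were higher as a list, with medians of 0.65 and 0.61 (camera with BH, adjusted p = 0.0096 and 0.0285, and adjusted p = 0.28 and 0.418 with an estimated correlation), the latter 0.19 without replicate 2 of 8 h. Of these 7 genes 0 passed at 3 h by edgeR, 1 by DESeq2, 2 at an unadjusted p under 0.05 and 1 adjusted over the list alone, and 1, GL2, rose at 8 h, 1 adjusted over the list alone. Without replicate 1 of 0 h 1 epidermis marker passed at 3 h. Of the 8 h calls 47.6 percent were higher under TMM and 57.5 percent under RLE. Without replicates 1 and 2 of 0 h and 1 and 2 of 3 h the 3 h count was 84, 61, 60 and 77. Without replicates 1 and 2 of 0 h and replicate 2 of 8 h the 8 h count was 415, 111 and 116. DESeq2 passed 346 genes at 3 h and the compared groups alone passed 1072. Each of YUC8, YUC9, BXL1, BEE1, DWF4, PIN4 and IBH1 at 3 h, and of ASN1, YUC9, GL2, DFL1, DET2, BRL3, MCM2, RNR1 and PIN4 at 8 h, failed without at least 1 of these libraries, GL2 without replicate 2 of 0 h or 8 h.

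In the endodermis (pSCR), PIN4 (AT2G01420, chromosome 2, 180105 to 183328) fell to 7.59 ± 0.746 CPM at 3 h and 6.97 ± 0.85 at 8 h from 24.4 ± 6.08. PLT2, a factor of the root stem cell niche, fell to 2.79 ± 0.0709 and 3.36 ± 0.131 CPM from 10.5 ± 3.76. At 3 h RTFL15, a small peptide gene, fell (-3.29) and MDHAR, an ascorbate-recycling enzyme, rose to 30.9 ± 4.22 from 13.3 ± 1.25 CPM. In all, 3 genes rose and 6 fell at 3 h, and 2 rose and 12 fell at 8 h, by the edgeR quasi-likelihood test with BH, with PIN4 at adjusted p of 0.000142 and 7.13e-05. Brassinosteroid synthesis genes were lower as a list at 3 h (adjusted p = 9.8e-05 by camera with BH, and adjusted p = 0.0111 with an estimated correlation), with 0 of the list passing over all genes by edgeR, 0 by DESeq2, 4 at an unadjusted p under 0.05 and 3 adjusted over the list alone. PIN4 passed without each library in turn, but PLT2, RTFL15 and MDHAR did not. The count at 3 h was 5 without replicate 2 of 0 h and 3 and 4 without replicates 1 and 2 of 3 h. At 8 h it was 9 without replicate 2 of 0 h and 9 and 6 without replicates 1 and 2 of 8 h. DESeq2 passed 22 and 40 genes and the compared groups alone 0 and 0.

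In the stele (pSHR), 4 genes changed at each time. AT2G46850, named after its values were seen like the other loci here, fell at both times (-3.73 ± 0.419 and -2.55 ± 0.38), and at 3 h AT4G33800 fell (-2.36), while AT2G42060 and XTH33 rose by 1.58 and 2.4. At 8 h AT5G62210 and AT5G38940 fell (-3.04 and -3.78), and SULTR1;1 rose from 0 counts at 0 h to 18 and 26 counts, at least 12.4-fold against a floor of 3 counts over the group. The edgeR quasi-likelihood test with BH gave AT2G46850 adjusted p of 1.25e-05 and 0.00247. The list of brassinosteroid breakdown was higher at both times (adjusted p = 0.0126 and 0.000562 by camera with BH, and adjusted p = 0.387 and 0.139 with an estimated correlation), with 0 of 5 passing over all genes by edgeR, 0 by DESeq2, 2 and 4 at an unadjusted p under 0.05 and 2 at each time adjusted over the list alone. Root hair markers were higher as a list at 8 h, with a median of 0.47 (camera with BH, adjusted p = 0.00413, and adjusted p = 0.741 with an estimated correlation), and of 0.27 without replicate 1 of 8 h. Of these 11 genes 0 passed by edgeR, 0 by DESeq2, 2 at an unadjusted p under 0.05 and 0 adjusted over the list alone. The 3 h count was 1 and 8 without replicates 1 and 2 of 0 h and 2 without replicate 2 of 3 h. The 8 h count was 2 and 10 without replicates 1 and 2 of 0 h and 1 and 0 without replicates 1 and 2 of 8 h. DESeq2 passed 24 and 13 genes and the compared groups alone 95 and 77, and only AT2G46850 at 3 h, among the genes named, passed without each library in turn.

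**Figure D2:**
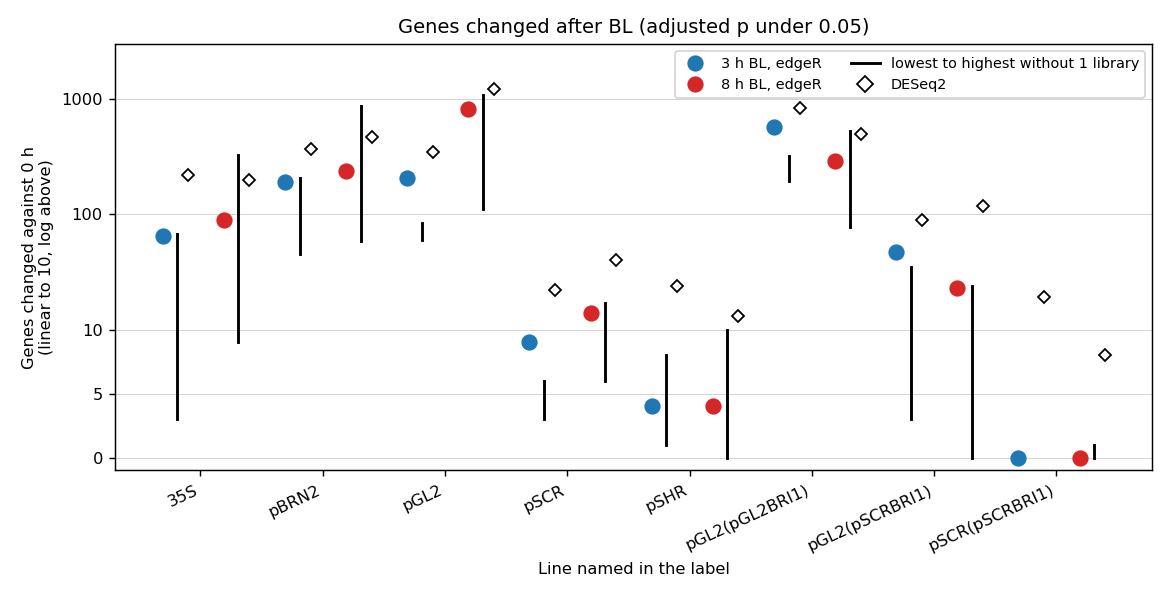
Number of genes changed after BL against 0 h in each line, on an axis linear to 10 and logarithmic above. Points are the edgeR test (blue 3 h, red 8 h), black lines run from the lowest to the highest count without 1 library, and white diamonds are DESeq2. The counts run from 0 in pSCR(pSCRBRI1) to 813 in pGL2 at 8 h.

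In pGL2(pGL2BRI1), where epidermal ribosomes were sampled and BRI1 was restored in the same cells, TCH4 rose to 52.5 ± 8.53 CPM at 3 h and 61 ± 8.27 at 8 h from 10.8 ± 3.77, XTH23 by 1.66 and 2.16, and the germin-like gene GLP9 by 3.06 and 3.59. BEE1 rose by 1.31 and 2.41. At 3 h IAA19 rose to 83.6 ± 22.7 from 32.1 ± 9.78 CPM, IAA6 by 2.73, the kinase gene CPK27 by 3.34 ± 0.359, the WRKY gene ABO3 by 5.80 and the heat shock gene HSP90.1 by 1.91. At 8 h the arabinogalactan gene AGP5 rose by 3.03 and the auxin-conjugating enzyme GH3.1 by 1.73. MYB55 fell to 2 ± 0.67 and 0.89 ± 0.63 CPM from 23.1 ± 2.77, and PIN4 to 1.5 ± 0.233 and 2.86 ± 1.07 CPM from 6.97 ± 1.45. BEH2 (-2.37 and -1.88), IBH1 (-2.0 and -2.14) and KRP2, an inhibitor of cell cycle kinases (-1.35 and -1.02), fell at both times. At 3 h IDL1 (-2.4), WRKY30 (-4.44), the brassinosteroid synthesis gene BR6OX2 (-2.24), PIN7 (-1.39) and the mitotic cyclin CYCB1;3 (-1.49) fell, and at 8 h XTH24 (-3.66) and CYP81H1 (-3.14).

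In all, 337 genes rose and 234 fell in pGL2(pGL2BRI1) at 3 h, and 156 rose and 136 fell at 8 h, by the edgeR quasi-likelihood test with BH, with MYB55 at adjusted p of 2.75e-07 and 4.53e-09. At 3 h the lists of brassinosteroid synthesis, auxin transport and cell cycle kinase inhibitors with D cyclins were lower, each also with an estimated correlation (adjusted p = 9.8e-05, 9.8e-05 and 0.0149 by camera with BH, and adjusted p = 0.0146, 0.0456 and 0.0456 with an estimated correlation). Of their members 2, 2 and 1 fell over all genes, and 6, 5 and 2 adjusted over the list alone. Without replicates 1 and 2 of 0 h and 1 and 2 of 3 h the synthesis genes were 1, 0, 0 and 0 and the transport genes 4, 1, 1 and 1. The 3 lists had 0, 1 and 0 genes with the compared groups alone and 0, 1 and 1 with read note libraries only. Expansin and XTH genes rose in 4 of 26 cases at 3 h and at 8 h in 3 with 1 lower (4 with 1 lower, and 6 with 2 lower, adjusted over the list alone), and as a list they did not pass (camera with BH, adjusted p = 0.31 and 0.258). The 3 h calls were 0 and 1 without replicate 2 of 0 h and replicate 2 of 3 h, and the 8 h calls 7 without replicate 2 of 8 h. With the compared groups alone they were 1 and 0, and with read note libraries only 0 and 2. Auxin response genes rose in 4 of 22 cases at 8 h and in 6 adjusted over the list alone (camera with BH, adjusted p = 0.0121, and adjusted p = 0.145 with an estimated correlation). They were 2 and 0 without replicates 1 and 2 of 0 h, 0 without replicate 1 of 8 h, 0 with the compared groups alone and 1 with read note libraries only. Endodermis markers also differed between these libraries. CASP1 was at 998, 459 and 1080 CPM without the read note and 56.8, 61.6 and 72.8 CPM with it. With the libraries of the read note only, an alternative chosen after the data were seen, 81 and 86 genes passed. The 3 h count was 322, 202, 238 and 193 without replicates 1 and 2 of 0 h and 1 and 2 of 3 h. The 8 h count was 86, 182, 77 and 523 without replicates 1 and 2 of 0 h and 1 and 2 of 8 h. TCH4, XTH23, IAA6, IAA19, BEE1, HSP90.1, BR6OX2, PIN7, IBH1 and CYCB1;3 failed at 3 h without replicate 2 of 0 h, and AGP5, GH3.1, BEH2, IBH1, PIN4 and KRP2 at 8 h without replicate 1 of 8 h. The compared groups alone passed 117 and 0 genes, and DESeq2 passed 492 at 8 h.

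In the libraries labelled pGL2(pSCRBRI1), whose markers are endodermal against the label, PEN2 (AT2G44490, chromosome 2, 18364756 to 18367725), a glucosinolate-degrading enzyme, rose at 3 h to 30.1 ± 7.54 from 8.64 ± 0.144 CPM, and PEN3 (AT1G59870), an ABC transporter, to 81.6 ± 16.9 from 22.5 ± 0.369 CPM. The peroxidase gene PER4, the receptor kinase gene CRK11, the zinc finger gene ZAT11, the amino acid transporter LHT1 and HSP90.1 rose by 2.46, 2.16, 2.05, 2.00 and 2.18, and MEE59 fell (-1.23). At 8 h PEN2 stood at 26.3 ± 6.24 CPM, EXO, a growth gene of the brassinosteroid response, and WRKY11 rose by 1.37 and 1.12, and LEA14 and the nitrilase gene NIT3 fell (-1.09 and -0.98). In all, 41 genes rose and 6 fell at 3 h, and 14 rose and 9 fell at 8 h, by the edgeR quasi-likelihood test with BH, with PEN2 at adjusted p of 0.000174 and 0.00087. The brassinosteroid synthesis list was lower at 3 h (adjusted p = 0.000886 by camera with BH, and adjusted p = 0.0431 with an estimated correlation), with 0 passing over all genes by edgeR, 0 by DESeq2, 3 at an unadjusted p under 0.05 and 1 adjusted over the list alone. The heat shock list was higher, with 1 of 7 passing, 0 without any 1 of the compared libraries, and 2 adjusted over the list alone (camera with BH, adjusted p = 9.94e-05, and adjusted p = 0.178 with an estimated correlation). The 3 h count was 3 and 6 without replicates 1 and 2 of 0 h and 9 without replicate 1 of 3 h. The 8 h count was 1 and 0 without replicates 1 and 2 of 0 h and 0 without replicate 2 of 8 h. Among the genes named only PEN2 at 3 h passed without each library, DESeq2 passed 90 and 119 genes, the compared groups alone passed 141 at 8 h, and the read note as a term gave 39 at 8 h.

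In pSCR(pSCRBRI1), where the endodermis was sampled and BRI1 was restored there, 0 genes passed at 3 h and 0 at 8 h by the edgeR quasi-likelihood test with BH. At an unadjusted p under 0.05 there were 925 and 528 genes, and DESeq2 passed 19 and 8. In this line the read note follows the replicate numbers. As a term per line, chosen after the data were seen, it left 0 at each time. A block of the replicate numbers in all lines passed more, as given below. Mitosis genes were lower as a list at 3 h, with a median of -1.15 (adjusted p = 2.18e-32 by camera with BH, and adjusted p = 0.0195 with an estimated correlation). Of its 21 members 16 were lower adjusted over the list alone, 0 over all genes by edgeR, 17 at an unadjusted p under 0.05 and 5 by DESeq2. The median was -0.71 without replicate 1 of 0 h. The values of the cyclin CYCB1;1, the cytokinesis gene KN and the mitotic kinase CDKB2;1 were -1.29 ± 0.344, -1.14 ± 0.318 and -1.06 ± 0.259, with adjusted p of 0.383, 0.489 and 0.278 over all genes by the edgeR quasi-likelihood test with BH. Without replicate 1 of 8 h the 8 h count was 1.

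**Figure D3:**
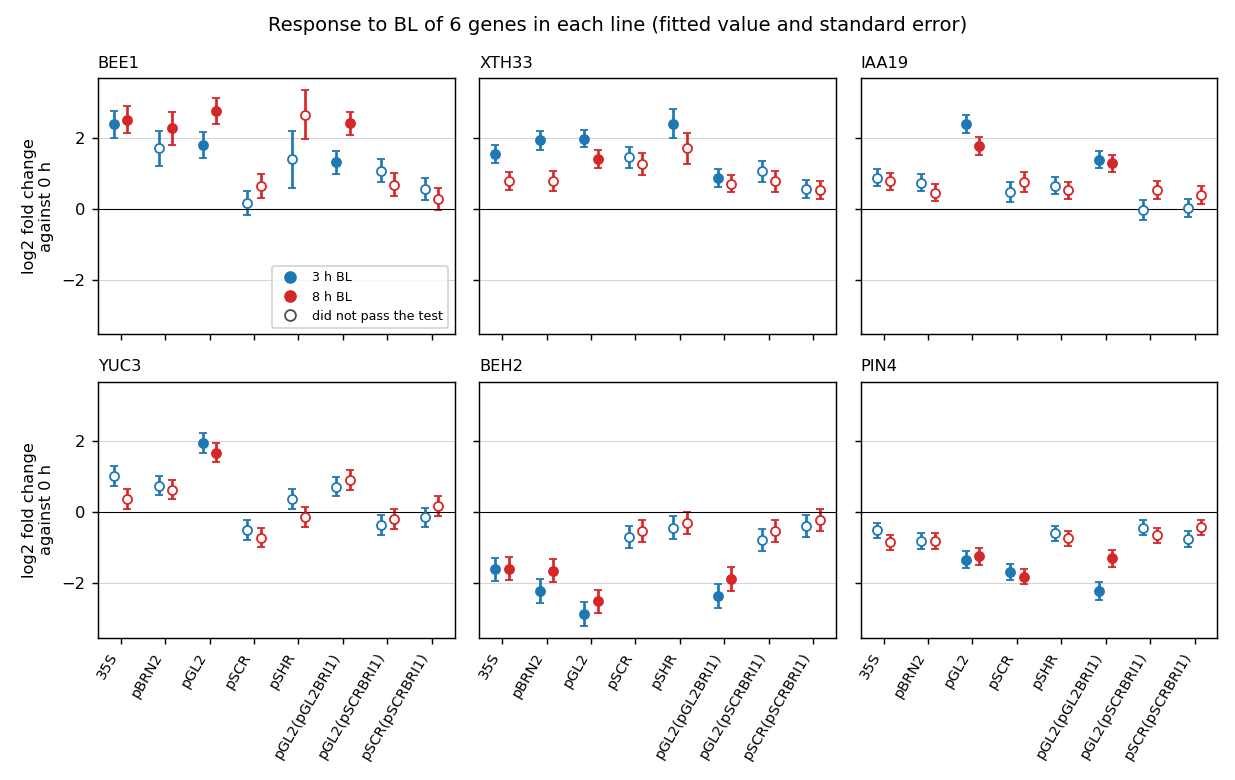
Log2 change against 0 h of BEE1, XTH33, IAA19, YUC3, BEH2 and PIN4 at 3 h (blue) and 8 h (red) in each line, as fitted value and SE. Open points did not pass the edgeR test. BEH2 is lower in 35S, pBRN2, pGL2 and pGL2(pGL2BRI1) at both times, and YUC3 is higher in pGL2 at both times.

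The complemented epidermis line pGL2(pGL2BRI1) was compared with Col-0 epidermis before BL. Among the genes higher than in pGL2 were XTH33 at 159 ± 45.5 against 26 ± 3.63 CPM, IAA19 at 32.1 ± 9.78 against 5.14 ± 0.61 CPM, and EXPA1, an expansin gene, SAUR9, an auxin-induced growth gene, and BEE1 by 3.12, 3.80 and 2.53. YUC8, YUC9 and YUC3 were higher by 3.21, 2.17 and 1.68, and NIC3 by 7.31. The iron reductase gene FRO5, WRKY54, GSTF14 and MCM2 were lower (-3.40, -2.32, -3.94 and -1.03). Auxin synthesis (5 of 9 higher), auxin response (10 of 22 higher, 1 lower) and brassinosteroid-linked bHLH genes (5 of 9 higher) were higher as lists. All 3 calls held with an estimated correlation (adjusted p = 8.44e-05, 8.44e-05 and 0.00512 by camera with BH, and adjusted p = 0.012, 0.0162 and 0.0212 with an estimated correlation). Adjusted over the list alone the counts were 5 with 1 lower, 13 with 2 lower, and 5. Auxin response calls numbered 6 without replicate 2 of pGL2. Expansin and XTH genes were higher in 7 of 26 cases and in 11 adjusted over the list alone (camera with BH, adjusted p = 8.44e-05, and adjusted p = 0.134 with an estimated correlation). Endodermis markers were higher in 10 of 13 cases and in 11 adjusted over the list alone (camera with BH, adjusted p = 8.44e-05, and adjusted p = 0.493 with an estimated correlation). CASP1 was at 528 ± 666 against 33.7 ± 7.56 CPM, and CASP2 and MYB36 (AT5G57620, chromosome 5, 23334817 to 23336566) were higher by 4.02 and 3.53. Without replicate 2 of pGL2(pGL2BRI1) 0 of these markers passed and MYB36 turned to -0.57, and 0 passed without replicate 1 or 2 of pGL2. In all, 1394 genes were higher and 996 lower by the edgeR quasi-likelihood test with BH, with XTH33 at an adjusted p of 1.02e-07. The count and the bHLH genes that passed fell without any of the compared libraries. With the read note library alone the bHLH median was 0.29, from 1.45, and the auxin synthesis and response medians 1.76 and 1.16.

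The libraries labelled pGL2(pSCRBRI1) were set against pGL2, with a profile that goes against the label. GL2 was at 1.81 ± 0.0219 against 86 ± 39.7 CPM, SCR at 221 ± 25.2 against 8.21 ± 2.36 CPM and CASP1 at 2530 ± 450 against 33.7 ± 7.56 CPM. WER, the wax and fatty acid gene KCS5, the auxin-induced gene AIR1 and the aquaporin-like gene NLM1 were lower (-5.35, -7.54, -7.62 and -7.27), and MYB36 and NIC3 higher by 6.21 and 8.72. Endodermis markers were higher in 12 of 13 cases (13 adjusted over the list alone), epidermis markers lower in 7 of 7, and cellulose synthesis genes lower in 9 of 9, 7 and 9 adjusted over the list alone, CESA6 at -2.08. Their adjusted p by camera with BH were 1.11e-05, 3e-05 and 5.53e-05, and with an estimated correlation the adjusted p = 0.423, 0.127 and 0.272. In all, 4781 genes were higher and 5273 lower by the edgeR quasi-likelihood test with BH, with GL2 at -5.57 ± 0.415 and an adjusted p of 2.23e-12. Because the 2 profiles are of different tissues, this comparison does not isolate the BRI1 transgene.

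In pSCR(pSCRBRI1) before BL, wall-loosening genes were higher than in pSCR. EXPA8 (AT2G40610, chromosome 2, 16948863 to 16950557), an expansin gene, was at 25.8 ± 1.21 against 0.765 ± 0.224 CPM, TCH4 at 29.2 ± 13.8 against 3 ± 0.806 CPM and XTH33 at 10.5 ± 0.505 against 1.21 ± 0.191 CPM. EXPA1, XTH5, the calmodulin-like touch gene TCH3, ACO1, NAC048 and YUC8 were higher by 4.53, 3.28, 4.30, 3.77, 4.77 and 2.59. PLT2, the actin gene ACT11 and the wall glycosyltransferase gene GATL6 were lower (-1.83, -1.33 and -1.61). Of the 26 expansin and XTH genes 12 were higher, 17 adjusted over the list alone, also with an estimated correlation (adjusted p = 7.12e-15 by camera with BH, and adjusted p = 0.00836 with an estimated correlation). The touch and wounding list was higher with 1 of 7 passing and 2 adjusted over the list alone (adjusted p = 0.00664 by camera with BH, and adjusted p = 0.257 with an estimated correlation), and 2 passed without replicate 1 of pSCR. Root hair markers were higher as a list, with a median of 0.53 (camera with BH, adjusted p = 0.0196, and adjusted p = 0.609 with an estimated correlation). It was 1.39 and 0.27 without replicates 1 and 2 of pSCR and 0.21 without replicate 1 of pSCR(pSCRBRI1). Of these 11 genes 1 was higher, 3 adjusted over the list alone, and 2, 0 and 0 passed without the same libraries. Epidermis markers had a median of 0.49, between 0.03 and 0.68 without each library in turn (camera with BH, adjusted p = 0.334). In all, 530 genes were higher and 97 lower by the edgeR quasi-likelihood test with BH, with EXPA8 at 5.06 ± 0.51 and an adjusted p of 1.66e-07. The count was 290 and 324 without replicates 1 and 2 of pSCR and 211 without replicate 1 of pSCR(pSCRBRI1), expansin and XTH genes numbered 7 without replicate 1 of pSCR, and XTH5 failed without replicate 1 of either line. DESeq2 passed 952 genes and the compared groups alone 187.

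The complemented lines were also compared with each other, pGL2(pGL2BRI1) against the libraries labelled pGL2(pSCRBRI1), whose markers go against the label. XTH17 was at 1760 ± 698 against 8.17 ± 1.79 CPM, with XTH18, the arabinogalactan gene AGP30, NLM1 and YUC9 higher by 7.72, 7.43, 7.05 and 5.17, and GL2 at 49.1 ± 10.6 against 1.81 ± 0.0219 CPM. The endodermal genes GPAT6, the laccase gene LAC5, SCR and CASP1 were lower (-3.89, -3.86, -2.85 and -2.26). Epidermis markers (7 of 7), auxin synthesis (7 higher and 1 lower of 9), auxin response (14 higher and 4 lower of 22) and brassinosteroid breakdown (4 of 5) were higher as lists, with the same counts adjusted over the list alone. Each had an adjusted p of 0.0451 by camera with BH and an estimated correlation. Endodermis markers were lower in 12 of 13 cases, 13 adjusted over the list alone, and mitosis genes in 15 of 21, 15 adjusted over the list alone (adjusted p = 0.383 and 0.43 with an estimated correlation, camera with BH). In all, 5155 genes were higher and 4644 lower by the edgeR quasi-likelihood test with BH, with XTH17 at an adjusted p of 1.1e-14. Without replicate 1 of pGL2(pGL2BRI1) the count was 6455, 1 endodermis marker and 3 mitosis genes passed, and CASP1 and SCR did not pass. Without replicates 1 and 2 of the labelled libraries 6 and 7 endodermis markers passed and CASP1 did not, and without replicate 2 5 mitosis genes passed.

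Responses to BL were compared between epidermis and endodermis by the difference of their log2 changes. YUC3 rose more in pGL2 than in pSCR at 3 h (difference 2.45 ± 0.39) and at 8 h (2.4 ± 0.39), with changes in pSCR of -0.50 ± 0.276 and -0.71 ± 0.278. At 3 h AT4G20320, named after its values were seen, differed by 1.94 ± 0.326, and at 8 h YUC8 by 2.72 ± 0.538, BXL1 by 3.86 ± 0.764 and LEA14 by -1.56 ± 0.302. The edgeR quasi-likelihood test with BH passed 2 genes at 3 h and 12 at 8 h, 6 higher and 6 lower, with YUC3 at adjusted p of 0.0126 and 0.00947. The auxin synthesis list responded more in pGL2 at both times (adjusted p = 0.00103 and 0.00182 by camera with BH, and adjusted p = 0.0139 and 0.0193 with an estimated correlation), with 1 and 2 genes passing over all genes and 2 and 2 adjusted over the list alone. Epidermis markers also differed as a list at 3 h, with a median of 0.53 (camera with BH, adjusted p = 0.0294, and adjusted p = 0.655 with an estimated correlation), and of 1.16 without replicate 2 of pSCR at 0 h or replicate 1 of pSCR at 3 h and 0.79 without replicate 2 of pSCR at 3 h. Of these 7 genes 0 passed by edgeR, 0 by DESeq2, 1 at an unadjusted p under 0.05 and 0 adjusted over the list alone. The 3 h auxin synthesis gene failed without any of the compared libraries except replicate 1 of pGL2 at 3 h and replicate 1 of pSCR at 0 h. Of the 8 h auxin synthesis genes 0 passed without replicate 1 or 2 of pGL2 at 0 h, replicate 2 of pGL2 at 8 h, replicate 2 of pSCR at 0 h or replicate 1 of pSCR at 8 h, and 1 without replicate 1 of pSCR at 0 h or replicate 2 at 8 h. Of the genes that changed in both lines, 5 at 3 h (1 higher in both and 4 lower in both) and 10 at 8 h (1 and 9), 100 percent had the same direction. Independent lists would share 0.015 and 0.029 at 3 h and 0.037 and 0.24 at 8 h. The 3 h count fell to 0 without any of 5 libraries (replicates 1 and 2 of pGL2 at 0 h, replicate 2 of pGL2 at 3 h, and both of pSCR at 3 h). It was 1 without replicate 1 or 2 of pSCR at 0 h. The 8 h count was 3, 0, 44 and 0 without replicates 1 and 2 of pGL2 at 0 h and 1 and 2 at 8 h. It was 2, 5, 4 and 3 without replicates 1 and 2 of pSCR at 0 h and 1 and 2 at 8 h. DESeq2 passed 15 and 40 genes and the compared groups alone 0 and 0.

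The responses of pGL2(pGL2BRI1) and of the libraries labelled pGL2(pSCRBRI1) were compared with the reservation that markers go against that label. At 3 h PIN4 fell more in pGL2(pGL2BRI1) (difference -1.79 ± 0.326) and PEN2 rose less (-1.77 ± 0.313), and AT1G76220 and AT2G43120, named after their values were seen, differed by -4.74 ± 0.772 and 1.74 ± 0.282. At 8 h AT1G76220 differed by -4.39 ± 0.715. The edgeR quasi-likelihood test with BH passed 4 genes at 3 h and 1 at 8 h, with PIN4 at an adjusted p of 0.0311. The auxin transport list was lower at 3 h (adjusted p = 1.02e-05 by camera with BH, and adjusted p = 0.0446 with an estimated correlation), with 1 of 11 passing, also adjusted over the list alone, and 0 without any 1 of the compared libraries. At 8 h 0 percent of the calls were higher under TMM and 66.7 percent, of 3 calls, under RLE. Of genes that changed in both lines, 22 at 3 h (18 higher and 4 lower) and 12 at 8 h (5 and 7), 100 percent had the same direction. Independent lists would share 0.66 and 0.067 at 3 h and 0.1 and 0.058 at 8 h. The 3 h count was 0 without replicate 1 of pGL2(pGL2BRI1) at 0 h or 3 h or replicate 1 of the labelled 0 h libraries, and 1 without replicate 2 of pGL2(pGL2BRI1) at 3 h, replicate 2 of the labelled 0 h libraries or either of the labelled 3 h libraries. The 8 h count was 0 without replicate 1 of pGL2(pGL2BRI1) at 0 h or 8 h, replicate 1 of the labelled 0 h libraries or replicate 2 of the labelled 8 h libraries, and 2 and 3 without replicate 2 of pGL2(pGL2BRI1) at 0 h and 8 h. DESeq2 passed 18 and 5 genes and the compared groups alone 0 and 0.

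Between pSCR(pSCRBRI1) and the libraries labelled pGL2(pSCRBRI1), whose markers are both endodermal, the responses of 0 genes differed at 3 h and 0 at 8 h by the edgeR quasi-likelihood test with BH. At an unadjusted p under 0.05 there were 400 and 472 genes, and DESeq2 passed 2 and 2. The mitosis list was lower in the response of pSCR(pSCRBRI1) at 3 h, with a median difference of -0.75 and 0 of 21 passing over all genes by edgeR, 3 at an unadjusted p under 0.05 and 0 by DESeq2 (adjusted p = 8.66e-13 by camera with BH, and adjusted p = 0.118 with an estimated correlation). The mitosis median was between -1.20 and -0.33 without each library in turn, the latter without replicate 1 of pSCR(pSCRBRI1) at 0 h. The DNA replication list was also lower, with a median difference of -0.48 (adjusted p = 8.04e-07 by camera with BH, and adjusted p = 0.0576 with an estimated correlation), between -0.68 and -0.31 without each library in turn. Of its 10 genes 0 passed by edgeR, 0 by DESeq2, 1 at an unadjusted p under 0.05 and 0 adjusted over the list alone. The replication medians of the 2 lines were -0.28 in pSCR(pSCRBRI1), between -0.44 and -0.12 without each library in turn, and 0.26 in the labelled line, between 0.16 and 0.38. Without replicate 2 of the labelled 3 h libraries 1 gene passed, and at 8 h 2 and 1 passed without replicate 1 of the labelled 8 h libraries and replicate 1 of pSCR(pSCRBRI1) at 0 h.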

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

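All tests of explanations below were chosen after the results were seen, except the omission of each library in turn, and the results themselves come from comparisons fixed before the data were examined.

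The differences in BL response between lines that passed the test of the difference itself stand here as values. Between pGL2 and pSCR, 2 genes differed at 3 h, YUC3 by 2.45 and AT4G20320 by 1.94 on the log2 scale. At 8 h 12 genes differed, among them YUC3 by 2.4, YUC8 by 2.72, BXL1 by 3.86 and LEA14 by -1.56. Between pGL2(pGL2BRI1) and the libraries labelled pGL2(pSCRBRI1), 4 genes differed at 3 h, PIN4 by -1.79, PEN2 by -1.77, AT1G76220 by -4.74 and AT2G43120 by 1.74, and 1 gene differed at 8 h, AT1G76220 by -4.39. The last comparison sets epidermal markers against endodermal markers, against the label of the second line.

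The endodermal profile of the 6 libraries labelled pGL2(pSCRBRI1) was weighed first. A mixture of epidermal and endodermal RNA is argued against by the non-hair epidermis markers, whose median level was 2.47 percent of that in pGL2. An exchange with another group of the series is argued against because 0 of the 12 libraries labelled with an endodermal tag promoter carried epidermis markers at 20 percent or more of pGL2. In all, 6 of 6 libraries were closer to pSCR than to pGL2 of the same time, with correlations across genes of 0.983 to 0.988 against 0.822 to 0.837. A tag expressed in the endodermis, through a wrong label or another line, and a biological change of cell identity would both give this, so they cannot be told apart and both stay open.

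The endodermal markers in 3 of the 6 libraries of pGL2(pGL2BRI1) were weighed next. A sequencing batch marked by the read note, acting alike on every line, is argued against because in pGL2 the endodermis list differed by -0.26 between libraries without and with the note, against 3.51 in pGL2(pGL2BRI1). RNA of endodermal cells mixed into these libraries may account for the markers. The share of endodermal RNA that single endodermal genes call for at 0 h had an upper quartile 2.13 times its lower quartile over 396 genes, from 12.6 to 26.9 percent, with quartiles of 4.84 and 10.5 percent at 3 h and 12.6 and 21.8 percent at 8 h. The epidermis markers were lower in the same libraries by 26.5, 14.1 and 30.9 percent, and a mix during the preparation of these libraries and a wider activity of the tag promoter were not separated, nor was a biological explanation tested.

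The lower mitosis list at 3 h in pSCR(pSCRBRI1), with a median log2 change of -1.15, was weighed last. A single library is argued against for a decrease as such, since the median was between -1.56 and -0.71 without each library in turn. It stays open for the excess over other lines, as -0.71, without replicate 1 of 0 h, was near -0.65 in pGL2(pGL2BRI1). Fewer dividing cells in the sampled roots stays open, since how far this would lower each list was not measured. The median change of the DNA replication list was 24.2 percent of that of the mitosis list, and 14.8 to 37.5 percent without each library in turn. In the response difference from the labelled line it was 64.1 percent, and 43.4 to 140 percent without each library. Handling or time since the addition, without BL, cannot be told apart from BL, since 0 untreated libraries of 3 h are analysed here. A response to BL through BRI1 in the endodermis stays open and untested, and the median was also below 0 at 3 h in the other 7 lines.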

How the results depend on the processing

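The alternatives chosen after the data were seen are listed in the processing part, and all others were chosen before. Each group held 2 libraries. Of 247 calls of named genes, some of them named in several comparisons, 139 passed without each library in turn, 108 failed without at least 1 and 93 failed in a fit of the compared groups alone, while 0 failed by DESeq2. Over all settings, values of named genes kept their direction and their side of the threshold in 2907 cases, fell short of it in 456, newly passed in 3 and turned in 2. Counts of changed genes stayed within 1.5 times in 245 cases and moved further in 171, and list tests kept their outcome in 102 and lost a call in 98. Shares of shared calls with the same direction were unchanged in 61 cases. With an estimated correlation in camera 30 list outcomes were kept and 70 calls were lost. With fry, which does not compare a list with other genes, 72 outcomes were kept and 28 calls were lost. The kept outcomes include lists that passed in neither test. For the counts given below the cause was not tested, except where stated, and a fit of few groups or without a library rests on fewer samples.

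By DESeq2 the counts at 3 and 8 h of BL were 217 and 199 in 35S, 365 and 470 in pBRN2, 346 at 3 h in pGL2, 22 and 40 in pSCR, 24 and 13 in pSHR, 492 at 8 h in pGL2(pGL2BRI1), 90 and 119 in the libraries labelled pGL2(pSCRBRI1) and 19 and 8 in pSCR(pSCRBRI1). It passed 952 genes between pSCR(pSCRBRI1) and pSCR, and for response differences 15 and 40 between pGL2 and pSCR, 18 and 5 between pGL2(pGL2BRI1) and the labelled line, and 2 and 2 between pSCR(pSCRBRI1) and the labelled line.

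With only the compared groups, their own spread and far fewer degrees of freedom, the count was 9836 for pSHR against 35S and 187 between pSCR(pSCRBRI1) and pSCR. At 3 and 8 h it was 0 and 0 in 35S, 0 and 38 in pBRN2, 1072 at 3 h in pGL2, 0 and 0 in pSCR, 95 and 77 in pSHR, 117 and 0 in pGL2(pGL2BRI1) and 141 at 8 h in the labelled line. The response differences of pGL2 and pSCR, and of pGL2(pGL2BRI1) and the labelled line, gave 0 and 0 each.

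Replicate numbers were not taken to pair the libraries, since no label says that a number marks a shared batch and each comparison has 2 such pairs. The read note follows the numbers at all 3 times in pSCR(pSCRBRI1), changes number between times in pGL2 and pGL2(pGL2BRI1), and is the same for both replicates in the other 5 lines. As a term per line it left 0 and 0 genes in pSCR(pSCRBRI1). Same-numbered deviations correlated at 0.33 to 0.61 at both BL times in pBRN2, pSCR, the labelled line and pSCR(pSCRBRI1). A batch shared by number stays open there. In the other lines correlations ran from -0.57 (pGL2(pGL2BRI1) at 3 h) and -0.21 (35S at 8 h) to 0.63, and between lines from -0.32 to 0.099. With the replicate block the counts at 3 and 8 h were 706 and 283 in 35S, 764 and 763 in pBRN2, 486 and 1580 in pGL2, 27 and 47 in pSCR, 19 and 12 in pSHR, 1325 and 771 in pGL2(pGL2BRI1), 136 and 195 in the labelled line and 55 and 2 in pSCR(pSCRBRI1), and for response differences 9 at 3 h between pGL2 and pSCR, 25 and 3 between pGL2(pGL2BRI1) and the labelled line, and 2 and 5 between pSCR(pSCRBRI1) and the labelled line. Crossed pairing gave 864 in 35S at 8 h and 2091 in pGL2(pGL2BRI1) at 3 h.

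The read note as a term gave 7 in pSHR at 3 h, 39 in the labelled line at 8 h and 5 for the response difference of pGL2 and pSCR at 3 h. As a term per line it gave 130 and 170 in 35S, 367 and 380 in pBRN2, 39 at 8 h in pSCR, 17 and 7 in pSHR and 74 and 95 in the labelled line, and for response differences 11 and 26 between pGL2 and pSCR, 12 and 2 between pGL2(pGL2BRI1) and the labelled line and 2 at 8 h between pSCR(pSCRBRI1) and the labelled line. With read note libraries only, 81 and 86 genes passed in pGL2(pGL2BRI1) at 3 and 8 h, 990 against pGL2 and 7 for its response difference from the labelled line at 8 h, and MYB36 turned to -0.57 against pGL2, from 3.53. For that response difference at 8 h RLE scaling and no filter on low counts gave 3 and 3.

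Without each library in turn the counts at 3 h ran from 3 to 68 in 35S, 45 to 206 in pBRN2, 60 to 84 in pGL2, 3 to 6 in pSCR, 1 to 8 in pSHR, 193 to 322 in pGL2(pGL2BRI1) and 3 to 35 in the labelled line. At 8 h they ran from 9 to 328, 59 to 862, 111 to 1077, 6 to 17, 0 to 10, 77 to 523 and 0 to 24 in the same lines, and 0 to 1 in pSCR(pSCRBRI1). Before BL they ran from 433 to 1543 for pGL2(pGL2BRI1) against pGL2, 211 to 582 for pSCR(pSCRBRI1) against pSCR and 6455 to 8932 for pGL2(pGL2BRI1) against the labelled line. Response differences ran from 0 to 2 and 0 to 44 at 3 and 8 h between pGL2 and pSCR, 0 to 4 and 0 to 3 between pGL2(pGL2BRI1) and the labelled line, and 0 to 1 and 0 to 2 between pSCR(pSCRBRI1) and the labelled line. MYB36 in pGL2(pGL2BRI1) against pGL2 ran from -0.57 without replicate 2 of pGL2(pGL2BRI1) to 4.49. The total counts of the promoter lines against 35S, of the labelled line against pGL2 and of pSCR(pSCRBRI1) at 3 h moved by no more than 1.5 times. The higher counts of pSCR and pSHR against 35S moved further.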

Other observations

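The list tests below belong to comparisons fixed before the data were examined, the lists described were picked after their results were seen, and 0 further tests were added for them.

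Mitosis genes were lower as a list at 3 h of BL in each of the 8 lines under the preset correlation of camera with BH. Outside pSCR(pSCRBRI1), described above, the adjusted p were 2.17e-06 in 35S, 0.000313 in pBRN2, 0.00046 in pGL2, 5.31e-07 in pSCR, 0.0126 in pSHR, 5.78e-07 in pGL2(pGL2BRI1) and 3.42e-05 in the libraries labelled pGL2(pSCRBRI1), whose markers go against the label. With an estimated correlation the adjusted p = 0.379, 0.53, 0.633, 0.386, 0.896, 0.269 and 0.369. Over all genes 2 of the 21 genes fell in pGL2(pGL2BRI1), the cyclins CYCB1;3 and CYCA1;1, with 3 lower adjusted over the list alone, and the 2 calls numbered 0, 0, 1 and 0 without replicates 1 and 2 of 0 h and 1 and 2 of 3 h, and 0 with the compared groups alone or with read note libraries only. In the other 6 lines 0 passed by edgeR, with 7, 5, 0, 3, 1 and 0 at an unadjusted p under 0.05, and DESeq2 passed 1, in pBRN2. Heat shock genes were higher as a list at 3 h in pGL2(pGL2BRI1) and pSCR(pSCRBRI1), with medians of 1.34 and 0.83 (camera with BH, adjusted p = 0.00367 and 0.000182, and adjusted p = 0.221 and 0.272 with an estimated correlation). The first median was 0.80 without replicate 1 of 3 h and 0.58 with read note libraries only, and the second 0.26 without replicate 2 of 3 h. Of the 7 genes 1, HSP90.1, rose in pGL2(pGL2BRI1), 3 adjusted over the list alone, and 0 passed without replicate 2 of 0 h or either replicate of 3 h, with the compared groups alone or with read note libraries only. In pSCR(pSCRBRI1) 0 passed by edgeR, 3 at an unadjusted p under 0.05, 1 by DESeq2 and 2 adjusted over the list alone.

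Of the 15 ethylene genes 3 changed in pGL2 at 3 h, each a gene of the enzyme that makes the precursor of ethylene, by the edgeR quasi-likelihood test with BH and adjusted over the list alone. ACS5 rose to 50.8 ± 0.569 from 18.5 ± 3.05 CPM and ACS9 to 193 from 4 counts over the group, while ACS11 fell to 1 from 173 counts over the group. Without each compared library in turn 2 passed. The list did not move one way (camera with BH, adjusted p = 0.805). Genes of the circadian clock were higher as a list in 35S at 3 h, with a median of 0.24 (camera with BH, adjusted p = 0.0282, and adjusted p = 0.379 with an estimated correlation), and of 0.53 and 0.44 without replicate 1 of 0 h and replicate 2 of 3 h. Of the 11 genes 0 passed by edgeR, 0 by DESeq2, 4 at an unadjusted p under 0.05 and 2 adjusted over the list alone. Brassinosteroid signalling genes were lower as a list in pBRN2 at 3 h, with a median of -0.16, between -0.60 and -0.06 without each library in turn (camera with BH, adjusted p = 0.0295, and adjusted p = 0.0763 with an estimated correlation), where BEH2 fell, 2 passed without replicate 1 of 3 h, and 2 of 17 fell adjusted over the list alone. Before BL, the list of cell cycle kinase inhibitors with D cyclins was higher in pGL2(pGL2BRI1) than in pGL2, with 3 of 6 higher and 4 adjusted over the list alone (camera with BH, adjusted p = 0.00512, and adjusted p = 0.0212 with an estimated correlation). The 3 calls numbered 1 and 0 without replicates 1 and 2 of pGL2, 1 without replicate 1 of pGL2(pGL2BRI1) and 1 with the compared groups alone. DNA replication genes were lower there in 6 of 10 cases and in 7 adjusted over the list alone (camera with BH, adjusted p = 8.44e-05, and adjusted p = 0.0533 with an estimated correlation), and in 2 and 3 without replicate 2 of pGL2 and replicate 1 of pGL2(pGL2BRI1).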
